A study of Mus musculus with 39 samples.

How the data were processed

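The series holds 39 samples of intestinal epithelial cells from C57BL/6 mice of 8 to 12 weeks, raised conventionally (CR), germ-free (GF) or conventionalized after germ-free rearing (CV). Per the labels, ileum is the last 6 cm of the midgut, colon the last 6 cm of the hindgut, and duodenum the first 5 cm of the midgut. Accessible chromatin was measured by DNase-seq in 21 libraries and polyadenylated RNA by paired 50 bp RNA-seq in 18. Per the labels, nuclei were released with 0.1% NP-40 and digested at 37 °C for 2, 4 and 8 minutes without added DNase I, and 5 micrograms of DNA were pooled from those times. RNA libraries began from 2 micrograms of total RNA. The labels state no cell sort, strand, sequencing batch, or link between replicate numbers and animals. A p-value thus measures the spread between libraries, or between genes in camera and Fisher tests.

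RNA-seq values are FPKM (fragments scaled by transcript length in kilobases and by the mapped fragments of the library), per the file headers, which the authors made with Cufflinks on each library alone. The submitters' processing notes name TopHat2 2.0.8b, Cufflinks, Cuffdiff 2.0.2, CASAVA 1.8.2 and BWA, and the mm9 build, without giving a role to each. Each deposited peak list holds 100000 intervals of 1 library in the narrowPeak layout. Its peak signal is the value of the authors' peak caller on an unstated scale, and the deposited score and −log10 p columns were not used for any comparison. A list of fixed length carries no depth, so the depth of the DNase-seq libraries is unknown. For RNA-seq, if the authors' confidence bounds are counting errors alone, they imply from 8.6 M fragments (mega, GF colon 2) to 37.5 M (CR ileum 2) behind the deposited FPKM values.

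The tables mix gene symbols with entries assembled in each library. Entries were matched by symbol, or by mm9 position where an assembled entry covered at least 80% of a gene's span, the span made up at least 20% of the entry, and no second gene had 50% of its span inside it. Entries of 1 symbol were summed. Unnamed loci of at least 300 bp were kept when at least 2 tables gave the same start and end. Of 20619 genes and loci with a value in every library, 10785 reached 1 scaled FPKM in at least 2 libraries and were tested: 5966 named genes (55.3%) and 4819 unnamed loci (44.7%). Of these, 1409 (13.1%) overlap another locus, and 368 (3.4%) are listed at 0 in 1 library and at 5 or more in another. The strand is not stated, so values of overlapping loci are uncertain as to the gene. Genes with a FAIL or HIDATA status in any library were left out.

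FPKM values were scaled by median ratios across libraries (factors 0.807 to 1.339) and tested as log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3: 1 linear model with 6 groups (CR, GF and CV in each tissue; 12 residual degrees of freedom), contrasts, and empirical Bayes with a trend. The moderated test is 2-sided, and a gene is called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences, their standard errors (SE) and adjusted p come from that model, while means and SD are of scaled FPKM. Every group difference is relative to the median gene. FPKM as deposited, without scaling, moved the median log2 difference of all genes to 0.18 for CR minus GF colon, 0.22 for CR minus CV colon and 0.31 for colon minus ileum, from −0.01, −0.03 and 0.02.

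Simulated data of the same group sizes had 200 changed genes. Of those changed by a log2 of 1, 59% and 54% (CR and CV minus GF ileum) and 72% and 76% (in colon) were called. For a log2 of 2 the shares were 94%, 88%, 97% and 99%. Wrong calls made up 5.6%, 6.6%, 4% and 9.8% of calls in that order. All shares hold for the simulated genes alone.

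Fixed before the data were examined were the tests, 28 gene lists, and the rule for named genes. The lists are antimicrobial defence, MHC class II, interferon response, lipid absorption, PPAR targets, cholesterol biosynthesis, bile acid transport, xenobiotic metabolism, cell cycle, stem cell, goblet, Paneth, enteroendocrine, tuft and absorptive cell markers, mucin-type glycosylation, transport induced by short-chain fatty acids, circadian clock, immediate early and stress genes, T cell, B cell, myeloid, stroma, acinar pancreas and erythrocyte markers, small intestine and colon regional markers, and sex-linked transcripts. Lists with at least 5 tested members (24) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. They were tested again with an estimated correlation and with fry. Because camera with the preset correlation made 63 calls over 216 tests and the estimated correlation left 1, every list call carries the second adjusted p.

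Named genes are the 6 highest and 6 lowest log2 differences of each comparison with GF and of colon against ileum, among called genes with a mean of at least 5 scaled FPKM in the higher group and no overlap between the groups' libraries. Small RNAs were left out. For CR minus CV the number is 4 per direction, and for the tests of a difference between tissues the 5 smallest p-values. The 3 members of each list with the smallest p and Reg3g, Reg3b, Saa1, Duox2, Retnlb, Fut2, Angptl4, Cd74, Cyp3a11, Fabp6, Slc10a2, Muc2, Lgr5 and Mki67 were added where measured. Because many of the highest and lowest loci are unnamed, the same choice among genes with a symbol was added after the data were seen. Positions are mm9, and no gene annotation of that build was used beyond the spans in the tables.

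DNase-seq lists were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. For each pair of libraries, the share of peaks of one that overlap a peak of the other by at least 1 bp was averaged over both directions. Shares were compared by exact permutation of the library labels. Peaks of a tissue were merged into regions, and regions present in every list of a group and in none of the other were counted for the real and all other splits of the libraries. Peaks were also counted within 10 kb of each gene. The overlap code returned 7 of 7 known answers on simulated lists.

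Alternatives were a pseudocount of 0.1, no filter and a filter of 5 scaled FPKM, FPKM as deposited, quantile normalization, a fit per tissue, library weights, replicate numbers as a block, leaving out each library, the 50% of peaks with the highest signal, an overlap of 50%, and 2 or 50 kb around genes. A further 6 were chosen after seeing the data: GF colon as its Y-expressing library alone, named genes alone, loci at 0 and at 5 or more left out, overlapping loci left out, a fit without CV, and 150 bp windows around peak summits.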

Results

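RNA-seq covered the ileum of 4 CR, 2 GF and 3 CV libraries and the colon of 3 libraries from each of the same groups of mice. DNase-seq covered the ileum of 4 CR, 3 GF and 3 CV libraries, the colon of 3 libraries per group, and the duodenum of 2 CR libraries. CR mice carry microbes from birth, GF mice carry none, and CV mice were born without microbes and colonized later. Implied RNA-seq fragments ran from 8.6 to 37.5 M, and peak list depth is unknown. The comparisons ask which transcripts of the gut epithelium differ with the microbiota, and whether accessible chromatin differs as well.

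The first principal component parted the RNA-seq libraries by tissue and held 61% of the variance. The second component (7.8%) placed the 6 CV libraries of both tissues between −31.03 and −20.66, and the 12 CR and GF libraries between −4.52 and 25.66. Correlations between libraries of a group, across genes, ran from 0.9398 to 0.9714.

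**Figure D1:**
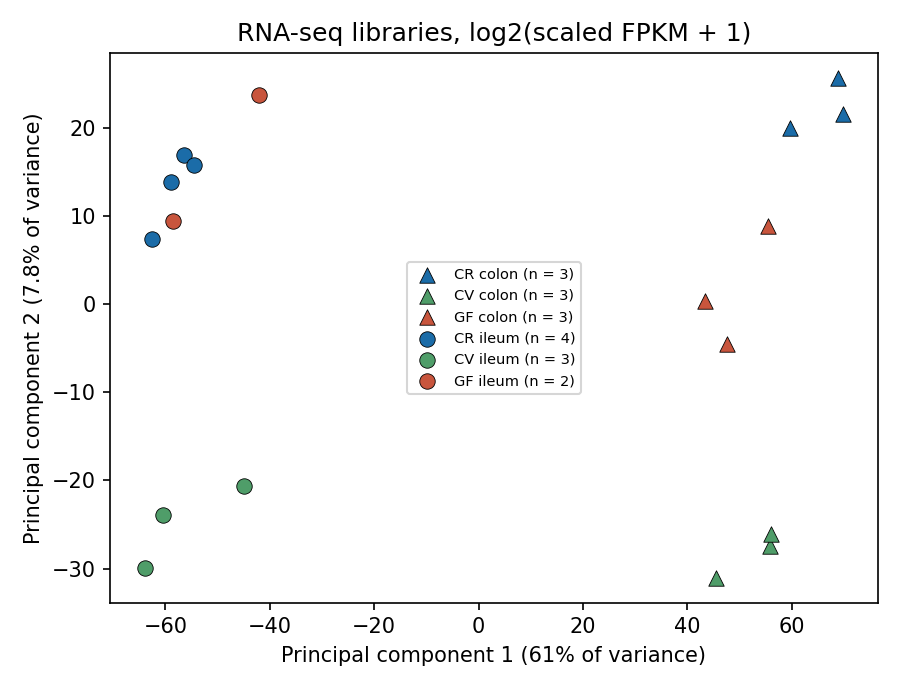
Principal components 1 and 2 of log2(scaled FPKM + 1), with 1 point per RNA-seq library, circles for ileum, triangles for colon, and blue, red and green for CR, GF and CV. The first component (61% of the variance) parts the tissues, and on the second (7.8%) all CV libraries lie at −20.66 or lower.

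In the ileum, microbes from birth went with more transcript of Pmepa1, a target and inhibitor of TGF-beta signalling, at 5.52 ± 2.24 in CR and 1.22 ± 0.277 in GF (log2 1.49, SE 0.26, adjusted p = 0.0388). Here and in the rest of this comparison, values are mean scaled FPKM ± SD with n = 4 for CR and n = 2 for GF. Psen2, a catalytic subunit of gamma-secretase on chromosome 1 (182157134 to 182186431), was lower in CR, at 5.78 ± 0.912 and 12.6 ± 2.59 (log2 −0.997, SE 0.18, adjusted p = 0.0388). Spsb4, which encodes a substrate receptor of a ubiquitin ligase, was lower as well, at 1.26 ± 0.779 and 5.39 ± 0.866 (log2 −1.54, SE 0.25, adjusted p = 0.0262). Bambi-ps1, a pseudogene on chromosome 2 whose reads cannot be assigned between it and its parent gene, was listed at 9.42 ± 6.19 and 1.25 ± 0.0139 (log2 2.06, adjusted p = 0.0253). Mkrn2, which overlaps another locus and is therefore uncertain, was listed at 3.06 ± 0.5605 and 7.43 ± 0.879 (log2 −1.06, adjusted p = 0.0377). An unnamed locus on chromosome 16 (4037144 to 4040024, between Nlrc3 and 4930455F16Rik) was at 12.8 in CR and listed at 0 in both GF libraries. Pmepa1 lost its call without CR ileum 1, 2 or 3, GF ileum 1 or 2, CV ileum 2, CR colon 2 or 3, GF colon 1 or 3 or CV colon 1, 2 or 3 (adjusted p 0.0501 to 0.154). Psen2 lost it without CR ileum 1, 3 or 4, GF ileum 1, CV ileum 1 or 2, GF colon 1 or 3 or CV colon 1 or 2 (adjusted p 0.0517 to 0.425), Spsb4 without CR ileum 1, 3 or 4 or GF ileum 1 or 2 (adjusted p 0.0527 to 0.109) and Bambi-ps1 without GF ileum 1 (adjusted p = 0.14). For Mkrn2 the call was lost without CR ileum 2, 3 or 4, GF ileum 1, CV ileum 2, CR colon 2, GF colon 1 or 3 or CV colon 1, 2 or 3 (adjusted p 0.0517 to 0.31).

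Angptl4, Reg3g, Reg3b, Saa1 and Fut2, which are known to respond to microbes, did not pass the test in the ileum. Angptl4, a secreted inhibitor of lipoprotein lipase, was at 26.9 ± 12.01 in CR and 139.6 ± 112 in GF (log2 −2.17, SE 0.47, adjusted p = 0.0981). Values of the antimicrobial lectins were 1844 ± 774 and 1236 ± 144 for Reg3g (adjusted p = 0.878) and 4391 ± 1783 and 3777 ± 313 for Reg3b (adjusted p = 0.992). The acute phase gene Saa1 was at 46.4 ± 57.2 and 1.89 ± 0.556 (adjusted p = 0.403). The fucosyltransferase gene Fut2 was at 10.4 ± 17.97 and 1.003 ± 0.0695 (adjusted p = 0.588), with 37.3 in CR ileum 1 against 1.15 to 1.52 in the other CR libraries. Gata4, a transcription factor of the proximal small intestine, was at 7.78 ± 1.44 and 1.33 ± 0.336 (log2 1.91, adjusted p = 0.0616). Vnn1, a pantetheinase under PPAR control, was at 104 ± 24.4 and 48.8 ± 4.95 (log2 1.06, adjusted p = 0.0923). Fgf15, the ileal hormone that lowers bile acid synthesis, was at 26.5 ± 27.1 and 0.462 ± 0.3601 (adjusted p = 0.141). Fabp6, the ileal bile acid-binding protein, and Slc10a2, the apical bile acid transporter, had adjusted p = 0.758 and 0.797. For Cyp3a11, Retnlb, Lgr5 and Mki67 the adjusted p ran from 0.441 (Mki67) to 0.897 (Lgr5). Duox2, Cd74 and Muc2 were not among the genes tested.

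In all, 12 of 10785 genes and loci were called in this comparison, 5 higher and 7 lower in CR, and 1135 had an unadjusted p under 0.05. The groups' libraries did not overlap for any of the 12, where chance gives 13.3% for an unselected gene. Here and in the comparisons that follow, such counts largely restate the calls. Called genes are selected for a difference between these same libraries, and the share over all tested genes was not counted. FPKM as deposited gave 5 higher and 3 lower. Without GF ileum 2 the count was 100, without GF colon 2 it was 19, without CR ileum 3 it was 7. Each of the 9 called genes and loci named by the rule lost its call in at least 2 of the 30 to 33 settings in which it was tested.

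Markers of T cells and intraepithelial lymphocytes were higher in CR ileum as a list: all 21 tested members had a positive difference, with a median log2 of 1.28 (adjusted p = 5.41e-14, or 0.741 with an estimated correlation). None was called over all genes, and 17 adjusted over the list alone. Cd7 was at 12.4 ± 9.99 and 1.67 ± 0.718 and Ptprc, the pan-leukocyte phosphatase, at 6.02 ± 5.58 and 0.779 ± 0.1704. Tuft cell markers such as Sh2d7 (9.44 ± 8.76 and 2.75 ± 1.096) had 13 of 13 positive differences (median 0.87, adjusted p = 8.59e-07, or 0.741 with an estimated correlation). MHC class II genes, with H2-Aa at 207 ± 229 and 14.9 ± 15.1 and H2-Eb1 at 108 ± 119 and 10.01 ± 7.45, had a median of 1.77 (adjusted p = 0.022, or 0.771 with an estimated correlation). The median was 0.836 without CR ileum 4 for the T cell list and 0.422 without CR ileum 1 for the tuft cell list. For MHC class II it was 1.042 without CR ileum 1, 1.058 without CR ileum 4 and 1.121 without GF ileum 2. Of 9 lists called in this comparison, 4 were called without CR ileum 1 and 2 without GF ileum 2.

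Smaller list medians above 0 were called for interferon response (0.49, 24 of 27 positive, adjusted p = 0.00315) and cell cycle genes (0.22, adjusted p = 0.0245). Lipid absorption was called too (0.37, adjusted p = 0.0239), with the chylomicron protein gene Apob at 346 ± 261 and 116 ± 60.7. The same holds for absorptive enterocyte genes (0.26, with adenosine deaminase gene Ada at 93.7 ± 43.8 and 20.6 ± 11.6, adjusted p = 0.0266) and small intestine regional markers (0.48, adjusted p = 0.0245). Goblet cell markers had a median of −0.39, with 7 of 7 negative (adjusted p = 0.022). With an estimated correlation the adjusted p was 0.814 for interferon response, 0.771 for lipid absorption, 0.854 for cell cycle, 0.814 for absorptive enterocyte, 0.771 for regional and 0.741 for goblet genes. No member of these lists was called over all genes, and adjusted over the list alone 2 absorptive and 2 regional genes were.

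The remaining lists were not called. Median log2 and adjusted p were 0.28 and 0.07 for antimicrobial defence, −0.06 and 0.967 for PPAR targets, −0.18 and 0.2 for cholesterol biosynthesis, −0.33 and 0.07 for xenobiotic metabolism, and −0.03 and 0.735 for stem cell markers. They were 0.12 and 0.518 for enteroendocrine markers, 0.00 and 0.518 for mucin-type glycosylation, 0.13 and 0.735 for the circadian clock, −0.09 and 0.741 for immediate early and stress genes, 0.55 and 0.0831 for myeloid markers, and 0.26 and 0.735 for sex-linked transcripts. Median, mean and test differed in sign for bile acid transport (median −0.27, mean 0.38, test upward, adjusted p = 0.741) and stroma (median 0.04, mean −0.05, test downward, adjusted p = 0.741). They differed as well for colon regional markers (median −0.02, mean 0.02, adjusted p = 0.931) and transport induced by short-chain fatty acids (median −0.03, mean −0.01, test upward, adjusted p = 0.798). Paneth (3 tested), B cell (2), acinar pancreas (4) and erythrocyte markers (1) had too few members for a list test, and none of these genes was called over all genes. Adjusted over the list alone, 1 PPAR target and 1 bile acid gene were higher, and 1 PPAR target, 1 Paneth, 2 myeloid and 1 stroma gene lower.

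**Figure D2:**
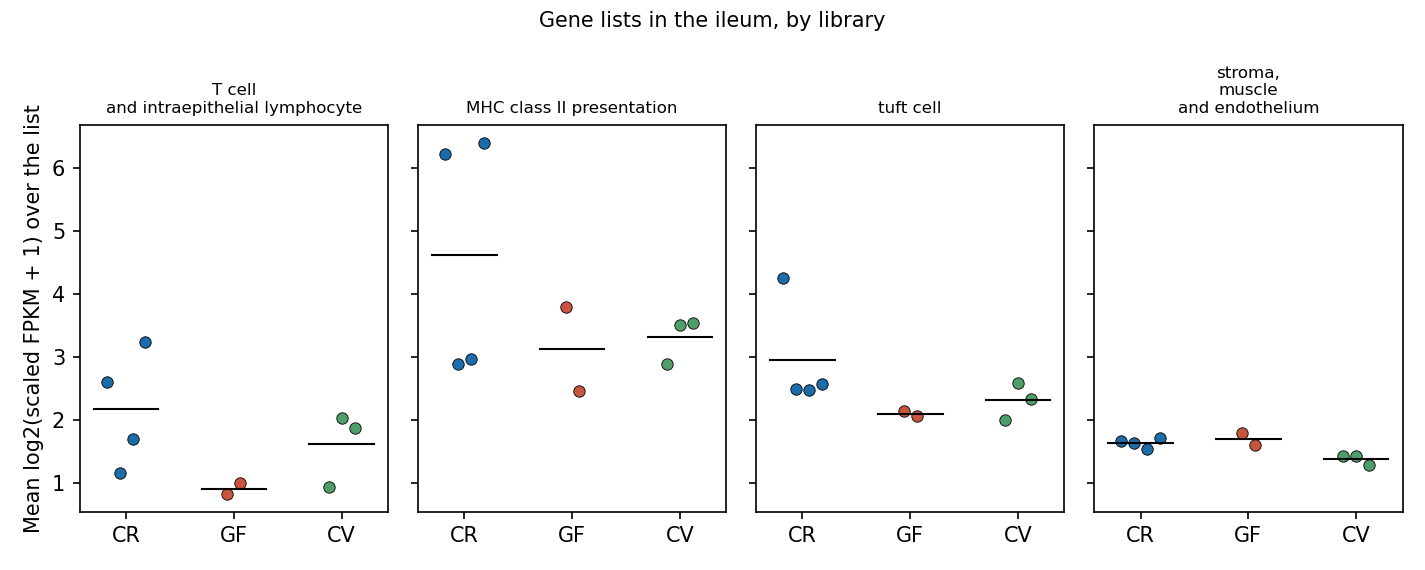
Mean log2(scaled FPKM + 1) over the T cell, MHC class II, tuft cell and stroma lists in each ileum RNA-seq library (points) and group means (lines). T cell scores were 1.14 to 3.24 in CR and 0.812 and 0.986 in GF, while stroma scores were 1.54 to 1.71 and 1.59 and 1.79.

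In the colon, genes of bile acid uptake were lower in CR than in GF mice. Fabp6 (chromosome 11, 43409613 to 43415013) was at 10.7 ± 6.06 in CR and 304 ± 25.96 in GF scaled FPKM (log2 −4.81, SE 0.59, adjusted p = 6.42e-04). Here and in the colon comparisons that follow, values are mean ± SD with n = 3 per group. Slc10a2 was at 5.505 ± 6.98 and 45.9 ± 26.1 (log2 −3.27, SE 0.69, adjusted p = 0.0233), and Osta, a subunit of the basolateral bile acid exporter, at 16.2 ± 17.1 and 115 ± 52.6 (log2 −3.17, SE 0.52, adjusted p = 0.00598). Its partner Ostb, which overlaps another locus, was at 48.1 ± 18.2 and 129 ± 46.4 (log2 −1.41, adjusted p = 0.019). All 6 tested genes of bile acid transport had a negative difference, 4 were called over all genes and 4 adjusted over the list alone (median −2.29, adjusted p = 1.97e-05, or 0.0742 with an estimated correlation). Fabp6 was called in every setting, Slc10a2 lost its call without CR colon 2 or 3 or GF colon 1 or 3 (adjusted p 0.0694 to 0.103) and Ostb without CR colon 2 or 3 (adjusted p 0.0595 to 0.0775).

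Other transcripts typical of the small intestine were lower in CR colon as well. Apoa1, the main protein of high-density lipoprotein, was at 1.09 ± 0.882 and 73.3 ± 49.1 (log2 −4.91, SE 0.94, adjusted p = 0.0162). Of the brush border enzymes, Sis (sucrase-isomaltase) was at 0.518 ± 0.516 and 15.6 ± 5.07 (log2 −3.45, SE 0.62, adjusted p = 0.0108). Anpep (aminopeptidase N) was at 1.97 ± 0.959 and 39.4 ± 30.2 (log2 −3.56, SE 0.71, adjusted p = 0.0187). Of 17 small intestine regional markers, 7 were called lower over all genes and 9 adjusted over the list alone, with a median of −1.92 (adjusted p = 1.62e-07, or 0.146 with an estimated correlation). Among 13 absorptive enterocyte genes 3 were called lower (6 over the list alone; median −0.94, adjusted p = 1.97e-05, or 0.334 with an estimated correlation). Lipid absorption genes had a median of −1.06, with Apob at 1.83 ± 0.386 and 13.4 ± 7.76 (2 of 17 lower, 3 over the list alone; adjusted p = 0.0126, or 0.484 with an estimated correlation). Apoa1 lost its call without CR colon 2 or GF colon 3 (adjusted p 0.0663 to 0.0691), Sis without CR colon 2 (adjusted p = 0.0532) and Anpep without CR colon 2 or 3 or GF colon 3 (adjusted p 0.0566 to 0.0775). Apob lost it without CR ileum 2, CV ileum 1 or 3, CR colon 1, 2 or 3, GF colon 1 or 3 or CV colon 1, 2 or 3 (adjusted p 0.05 to 0.172).

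Angptl4 (chromosome 17, 33911844 to 33918520) was at 0.448 ± 0.164 in CR and 5.495 ± 0.798 in GF (log2 −2.16, SE 0.44, adjusted p = 0.0198). Vnn1 was at 1.15 ± 0.462 and 4.75 ± 1.36 (log2 −1.41, SE 0.20, adjusted p = 0.00269). Both are PPAR targets, a list with 15 of 17 negative differences, 2 calls over all genes and 8 adjusted over the list alone (median −0.42, adjusted p = 9.44e-05, or 0.334 with an estimated correlation). Of the xenobiotic metabolism genes, the retinaldehyde dehydrogenase gene Aldh1a1 was at 42.5 ± 9.27 and 194 ± 60.1 (log2 −2.13, SE 0.35, adjusted p = 0.00598). Tgfbi, a secreted matrix protein induced by TGF-beta, was at 1.48 ± 1.41 and 21.4 ± 7.18 (log2 −3.27, SE 0.35, adjusted p = 1.25e-04). The stress-responsive phosphatase gene Dusp1 (7.43 ± 5.37 and 25.4 ± 11.1) and the transcription factor gene Fosb (1.28 ± 1.67 and 9.65 ± 3.67) had adjusted p = 0.0372 and 0.0359. Immediate early and stress genes as a list had a median of −0.32 (adjusted p = 0.0167, or 0.57 with an estimated correlation), and enteroendocrine markers one of −0.37, with 16 of 17 negative (adjusted p = 0.0167, or 0.638 with an estimated correlation). Vnn1, Tgfbi and Aldh1a1 were called in every setting. Angptl4 lost its call without CR colon 2 or 3 or GF colon 3 (adjusted p 0.0663 to 0.0773), Dusp1 without CR ileum 4, CR colon 2 or 3 or GF colon 1, 2 or 3 (adjusted p 0.0508 to 0.156) and Fosb without CR colon 2 or 3 or GF colon 1, 2 or 3 (adjusted p 0.0579 to 0.147).

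Higher in CR colon was Retnlb, a goblet cell lectin-like protein induced by microbes, at 301 ± 139 in CR and 38.98 ± 6.77 in GF (log2 2.80, SE 0.63, adjusted p = 0.0326). The endoplasmic reticulum chaperone gene Fkbp11 was at 16.9 ± 3.08 and 4.703 ± 1.27 (log2 1.66, SE 0.29, adjusted p = 0.00922). The calcium-binding protein gene S100a14 was at 80.4 ± 10.1 and 28.4 ± 8.28 (log2 1.498, SE 0.24, adjusted p = 0.00598). Itga5, a subunit of the fibronectin receptor, was at 5.93 ± 0.5796 and 1.71 ± 0.4598 (log2 1.36, SE 0.19, adjusted p = 0.00194). Ifitm3, an antiviral gene induced by interferon, was at 36.98 ± 22.2 and 6.47 ± 2.63 (adjusted p = 0.0322), and Capg, an actin-capping protein gene, at 35.2 ± 24.9 and 7.07 ± 1.85 (adjusted p = 0.0108). Cell cycle genes had 32 of 33 positive differences, 1 call over all genes and 5 adjusted over the list alone (median 0.51, adjusted p = 1.10e-07, or 0.413 with an estimated correlation). The called one is the mitotic cyclin gene Ccnb1 (11.7 ± 1.998 and 5.38 ± 0.793, adjusted p = 0.0427). Colon regional markers had a median of 0.52 (2 of 12 called, 5 over the list alone; adjusted p = 0.0015, or 0.146 with an estimated correlation). Of 12 lists called in this comparison, 6 were called without GF colon 2. Interferon response genes had a median of 0.45 (adjusted p = 0.0236, or 0.67 with an estimated correlation), and tuft cell markers one of 0.28 with all 13 positive (adjusted p = 0.0408, or 0.67 with an estimated correlation). S100a14 was called in every setting. Retnlb lost its call without CR colon 1 or 2 or GF colon 1 or 3 (adjusted p 0.0572 to 0.128), Fkbp11 without CR colon 2 (adjusted p = 0.0532) and Ifitm3 without CR colon 1 or 3 or GF colon 1 or 3 (adjusted p 0.0725 to 0.12). Ccnb1 lost it without CR ileum 2, 3 or 4, CV ileum 1, CR colon 2 or 3, GF colon 1, 2 or 3 or CV colon 2 (adjusted p 0.0512 to 0.163).

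Not called in the colon were Reg3b (87.96 ± 144 and 104 ± 41.3, adjusted p = 0.269) and Reg3g (21.2 ± 29.2 and 24.9 ± 11.03, adjusted p = 0.481). Nor were Saa1 (610.2 ± 239 and 1926 ± 1088, adjusted p = 0.461) and Ang4, an antimicrobial ribonuclease gene (454 ± 402 and 50.7 ± 17.1, adjusted p = 0.0618). Antimicrobial defence had a median of 0.41 and a mean of the opposite sign, −0.002 (adjusted p = 0.688). In that list Retnlb was called higher and Saa2 lower (0.616 ± 0.525 and 6.64 ± 5.68, adjusted p = 0.0198), the latter lost without CR colon 3 or GF colon 3 (adjusted p 0.0629 to 0.0867). Adjusted p was 0.769 for the proliferation marker Mki67, 0.96 for the stem cell receptor gene Lgr5, 0.894 for Fut2 and 0.711 for Cyp3a11. Of loci without a name, one on chromosome 12 (110779205 to 110809939, between Dlk1 and Mir673) was at 45.3 ± 7.99 in CR and 0.857 in GF. Trmt112, which overlaps another locus, was at 27.2 ± 3.25 in CR and listed at 0 in all GF libraries.

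The colon comparison called 253 genes and loci, 138 higher and 115 lower in CR, with no overlap between the groups' libraries for 251 (chance gives 10% of genes). Another split of these CR and GF libraries called 287. FPKM as deposited gave 390 higher and 94 lower. The count was 421 without CR colon 1, 63 without CR colon 2, 91 without CR colon 3, 120 without GF colon 1, 455 without GF colon 2 and 86 without GF colon 3. GF colon 2 and 3 listed the X-inactivation transcript Xist at 16.7 and 65.2 and the Y-linked Kdm5d, Eif2s3y and Uty at 0, whereas the other 16 RNA-seq libraries expressed Y-linked genes. Sex-linked transcripts were called as a list (adjusted p = 0.0408, or 0.413 with an estimated correlation). With GF colon 1, the library that expresses Y-linked genes, as the only GF colon library, an alternative chosen after seeing the data, the count was 280, and 104 of the 253 were among them.

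**Figure D3:**
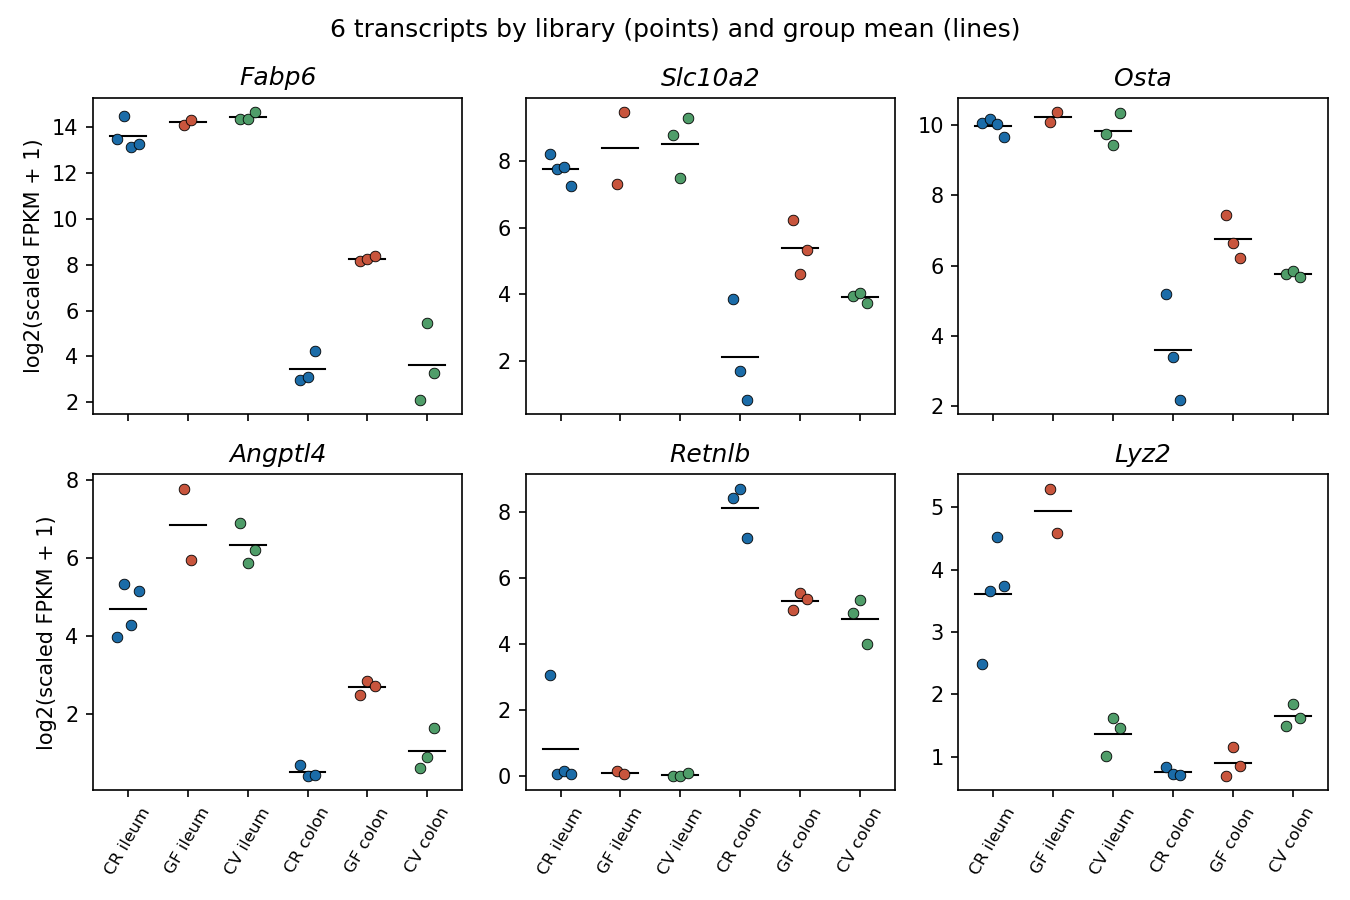
Log2(scaled FPKM + 1) of Fabp6, Slc10a2, Osta, Angptl4, Retnlb and Lyz2 in each RNA-seq library of the ileum and colon, with points for libraries and lines for group means. In the colon, Fabp6 lay at 282 to 333 scaled FPKM in GF and at 6.95 to 17.7 in CR, and Lyz2 in the ileum lay at 1.02 to 2.09 in CV and at 22.9 and 38.3 in GF.

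Colonization after germ-free rearing went with a lower value of Lyz2, a lysozyme gene of myeloid cells, in the ileum: 1.62 ± 0.551 in CV and 30.6 ± 10.9 in GF (log2 −3.57, SE 0.40, adjusted p = 6.13e-05). Values of this comparison are means ± SD with n = 3 for CV and n = 2 for GF. Abcb1b, a drug efflux pump gene, was at 0.278 ± 0.303 and 6.17 ± 3.55 (log2 −2.42, SE 0.38, adjusted p = 0.00156). Csl, a citrate synthase-like gene on chromosome 10 (99220338 to 99222292), was at 0.248 ± 0.0664 and 14.4 ± 4.48 (log2 −3.59, SE 0.30, adjusted p = 2.29e-06). Higher in CV ileum was Fbxo6, which encodes a ubiquitin ligase subunit for glycoproteins, at 20.8 ± 8.02 and 2.58 ± 0.524 (log2 2.56, SE 0.30, adjusted p = 1.14e-04). The stress granule gene G3bp2 was at 33.7 ± 3.33 and 3.83 ± 0.0804 (log2 2.84, SE 0.48, adjusted p = 0.00288). Htatip2 was at 21.1 ± 2.38 and 4.02 ± 0.413 (adjusted p = 1.91e-04) and Pkig, an inhibitor of protein kinase A, at 30.7 ± 1.92 and 9.86 ± 2.61 (adjusted p = 2.69e-04). The spindle assembly gene Tpx2 was at 4.38 ± 2.28 and 0.388 ± 0.257 (adjusted p = 0.00147). Apex1, a DNA repair endonuclease gene on chromosome 14 that overlaps another locus, was listed at 0 in all CV libraries and at 8.904 ± 3.27 in GF. The unnamed locus on chromosome 6 (117850357 to 117875640, between Zfp239 and Fxyd4) was at 146 ± 3.78 and 6.48 ± 3.23.

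Reg3g, Reg3b, Saa1 and Angptl4 did not pass the test in the CV ileum. Reg3g was at 2292 ± 922 and 1236 ± 144 (adjusted p = 0.662) and Reg3b at 6898 ± 2568 and 3777 ± 313 (adjusted p = 0.787). Saa1 was at 16.3 ± 13.3 and 1.89 ± 0.556 (adjusted p = 0.401) and Angptl4 at 83.6 ± 32.1 and 139.6 ± 112 (adjusted p = 0.604). T cell markers had 21 of 21 positive differences with none called (median 0.57, adjusted p = 0.0125, or 0.976 with an estimated correlation). All 7 goblet cell genes had negative ones (median −0.52, adjusted p = 0.0174, or 0.976 with an estimated correlation), and 1 was called adjusted over the list alone. Camera called these 2 lists, 1 without CV ileum 1, 4 without CV ileum 3 and 0 of 24 without GF ileum 2. In all, 128 genes and loci were higher and 67 lower in CV ileum, with no overlap between the groups' libraries for any of these (chance gives 20% of genes). Without GF ileum 2 the count was 1100 and without GF ileum 1 it was 127. Among the called, 27 of 96 with a name have the name of a gene copy, 59 overlap another locus and 25 are listed at 0 in 1 library and at 5 or more in another.

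The CV colon shared the low Fabp6 of the CR colon, at 18.1 ± 21.1 in CV and 304 ± 25.96 in GF (log2 −4.64, SE 0.59, adjusted p = 2.05e-04). Vnn1 was at 2.05 ± 0.325 and 4.75 ± 1.36 (log2 −0.89, adjusted p = 0.0328). Adh5, the formaldehyde-detoxifying dehydrogenase gene, was at 33.3 ± 3.95 and 67.6 ± 13.4 (log2 −0.99, adjusted p = 0.00187), while Angptl4 was at 1.19 ± 0.8597 and 5.495 ± 0.798 (adjusted p = 0.0814). Higher in CV colon was Ly6e, an antiviral membrane protein gene on chromosome 15, at 97.2 ± 26.4 and 2.82 ± 1.29 (log2 4.70, SE 0.52, adjusted p = 4.16e-05). Nfe2l1, a regulator of proteasome genes, was at 38.6 ± 2.301 and 6.37 ± 5.26 (log2 2.66, SE 0.48, adjusted p = 0.00495). Dclk1, a tuft cell kinase gene, was at 4.52 ± 1.28 and 0.771 ± 0.331 (log2 1.63, adjusted p = 0.026). The membrane mucin gene Muc1 was at 5.11 ± 0.989 and 2.41 ± 0.6396 (log2 0.85, adjusted p = 0.012). Retnlb was at 28.1 ± 12.2 and 38.98 ± 6.77 (adjusted p = 0.789). Vnn1 lost its call without GF colon 1 or 2 or CV colon 1, 2 or 3 (adjusted p 0.0675 to 0.147), Dclk1 without GF colon 1 or 2 or CV colon 1 or 2 (adjusted p 0.0627 to 0.123) and Muc1 without GF colon 1 or 2 or CV colon 2 (adjusted p 0.0507 to 0.0765).

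PPAR targets had 17 of 17 negative differences in CV colon, 1 called over all genes and 2 adjusted over the list alone (median −0.37, adjusted p = 1.84e-04, or 0.387 with an estimated correlation). Bile acid transport genes had a median of −1.05 (adjusted p = 0.0019, or 0.185 with an estimated correlation), with Slc10a2 at 14.1 ± 1.61 and 45.9 ± 26.1 (adjusted p = 0.365). Colon regional markers had a median of 0.63 (adjusted p = 0.0019, or 0.185 with an estimated correlation). The median of mucin-type glycosylation was 0.36 (adjusted p = 0.0258, or 0.401 with an estimated correlation) and that of cholesterol biosynthesis 0.43 (adjusted p = 0.0417, or 0.835 with an estimated correlation). Sex-linked transcripts were called too (adjusted p = 0.0447, or 0.401 with an estimated correlation). In place of these 6 list calls there were 10 without CV colon 1 and 3 without CV colon 3 or GF colon 3.

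The colon comparison of CV with GF called 122 genes and loci higher and 78 lower, with no overlap between the groups' libraries for 199 (chance gives 10% of genes), and no library moved that count by over 1.5 times. Names of gene copies made up 35 of the 113 called in colon that have a name. Of the 195 genes and loci called in ileum and the 200 in colon, 113 were called in both, all 113 in the same direction, against 3.62 for independent calls. Csl, Gm5148, BC002163 and Apex1 (lower in CV) and Fbxo6, Pkig, Tpx2, G3bp2 and D14Ertd449e (higher) are among those 113. In the colon, the calls of CR minus GF and CV minus GF shared 22 genes and loci in the same direction and 1 in the opposite one, against 1.56 higher and 0.832 lower for independent calls. Fabp6, Vnn1, Cxcl12, Hoxb7, Selenbp2 and Adh5 were lower in both, and Tmed3, Pla2g15, Tmem97 and Zfp750 higher. Both contrasts use the same GF libraries, and in 100 simulations of unchanged groups with such a shared control the overlap reached up to 34 (median 0). In the ileum the overlap was 0, from 12 and 195 calls by limma. At an unadjusted p under 0.05 the ileum contrasts held 1135 and 1943 genes and loci. Without GF ileum 2 the ileum overlap was 80 and without GF ileum 1 it was 9. It was 2 without CR ileum 4, CV ileum 1 or GF colon 2, and 1 without CV ileum 3, CR colon 3 or CV colon 3. Without CV colon 3 the colon overlap was 6, without CR colon 2 it was 8 and without CV colon 2 it was 9. It was 12 without CR colon 3 and 14 without CR ileum 4 or CV ileum 1.

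Mice colonized from birth and mice colonized later were compared directly. In the ileum, CR had more Gata4 (7.78 ± 1.44 in CR and 1.71 ± 0.735 in CV, n = 4 and 3, log2 1.72, SE 0.32, adjusted p = 0.0051). Lyz2 was higher in CR, at 12.7 ± 7.09 and 1.62 ± 0.551 (log2 2.24, SE 0.34, adjusted p = 7.65e-04). So was Gprc5a, a retinoic acid-induced receptor gene (23.8 ± 11.7 and 4.41 ± 2.85, log2 2.18, SE 0.39, adjusted p = 0.00405). Angptl4 was lower in CR ileum (26.9 ± 12.01 and 83.6 ± 32.1, log2 −1.64, SE 0.41, adjusted p = 0.0417). The glutathione transferase gene Gsta2 was lower as well (1.49 ± 0.723 and 9.28 ± 4.13, adjusted p = 0.0101). Enteroendocrine markers had a median of 0.60 with 15 of 17 positive, tuft cell markers 0.69 with 12 of 13, and T cell markers 0.54 with 20 of 21 (adjusted p = 0.00366 for each, or 0.749 with an estimated correlation). Cell cycle (median 0.26, adjusted p = 0.00763), interferon response (0.40, adjusted p = 0.0228) and myeloid genes (0.48, adjusted p = 0.0273) were called as well, with adjusted p = 0.749, 0.76 and 0.749 with an estimated correlation. In place of these 6 list calls there were 3 without CR ileum 4 and 0 of 24 by camera without CV ileum 1. The ileum comparison called 117 genes and loci higher and 194 lower in CR, with no overlap between the groups' libraries for 307 (chance gives 5.71% of genes), and 193 in all without CV ileum 1. Angptl4 lost its call without CR ileum 1 or 3, CV ileum 1, 2 or 3, CR colon 2 or 3, GF colon 1, 2 or 3 or CV colon 2 (adjusted p 0.0516 to 0.215), and Gsta2 without CV ileum 1 (adjusted p = 0.0733).

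In the colon, CR had more Retnlb than CV (301 ± 139 in CR and 28.1 ± 12.2 in CV, log2 3.34, SE 0.63, adjusted p = 0.00559). Ang4 was higher too (454 ± 402 and 40.3 ± 32.7, log2 3.37, SE 0.74, adjusted p = 0.014), a call lost without CR colon 2 or CV colon 1 (adjusted p 0.0706 to 0.0713). The spindle checkpoint gene Mad2l1 (14.5 ± 4.12 and 4.68 ± 0.338, adjusted p = 0.00283) and the proto-oncogene Myc (18 ± 3.97 and 7.21 ± 0.847, adjusted p = 0.0235) were higher in CR as well. The mitotic gene Birc5 was at 24.4 ± 7.71 and 10.9 ± 1.18 (adjusted p = 0.0199). Cell cycle genes had 32 of 33 positive differences, with 3 called higher and 1 lower over all genes and 10 and 1 adjusted over the list alone (median 0.56, adjusted p = 3.40e-07, or 0.935 with an estimated correlation). Lower in CR colon were the acute phase gene Saa2 (0.616 ± 0.525 and 14.3 ± 5.06, log2 −3.25, SE 0.41, adjusted p = 1.64e-04) and Ly6e (11.7 ± 7.58 and 97.2 ± 26.4, log2 −3.11, SE 0.52, adjusted p = 0.00235). Sis (0.518 ± 0.516 and 10.03 ± 11.4, adjusted p = 0.0323) and the proton pump gene Atp12a (26.1 ± 12.1 and 119 ± 85.2, adjusted p = 0.0315) were lower too. All 13 absorptive enterocyte genes had a negative difference (median −1.19, adjusted p = 0.00456, or 0.935 with an estimated correlation), and small intestine regional markers had a median of −1.24 (adjusted p = 0.00456, or 0.935 with an estimated correlation). Camera called these 3 lists, and 5 without CV colon 2. Myc lost its call without CR colon 2 or 3 or CV colon 1, 2 or 3 (adjusted p 0.0541 to 0.117), Birc5 without CR colon 2 or 3 or CV colon 1 or 3 (adjusted p 0.0614 to 0.109), Sis without CR colon 2 or 3 or CV colon 1 (adjusted p 0.11 to 0.125) and Atp12a without CR colon 2 or 3 or CV colon 2 or 3 (adjusted p 0.0505 to 0.152). Fabp6 was at 10.7 ± 6.06 and 18.1 ± 21.1 (adjusted p = 0.887).

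CR minus CV colon called 340 genes and loci higher and 363 lower, with no overlap between the groups' libraries for 691 (chance gives 10% of genes), and FPKM as deposited gave 1211 and 226. The count was 1304 without CR colon 1, 299 without CR colon 2, 266 without CR colon 3, 316 without CV colon 1, 428 without CV colon 2 and 388 without CV colon 3. Between the tissues, 140 calls of CR minus CV were shared, 137 in the same direction, against 20.3 for independent calls.

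Whether the effect of microbes differs between colon and ileum was tested as an interaction. For CR minus GF it was called for Vnn1 (log2 −2.47, SE 0.30, adjusted p = 0.00111), Tgfbi (log2 −3.52, SE 0.51, adjusted p = 0.00596) and the overlapping Trmt112. It was called as well for the chemokine gene Cxcl12 (log2 −1.71, adjusted p = 0.0151), Arrdc4 (log2 −1.24, adjusted p = 0.0119) and S100a14 (log2 2.17, adjusted p = 0.0151). Vnn1 was lower in CR colon, and its difference in the ileum had the opposite sign. For Fabp6 (log2 −4.20, adjusted p = 0.0532), Sis (log2 −4.08, adjusted p = 0.0656), Apoa1 (log2 −5.39, adjusted p = 0.0927), Osta (log2 −2.93, adjusted p = 0.0927) and Angptl4 (log2 0.00, adjusted p = 1) the tissues were not shown to differ. For CV minus GF the interaction was called for Lyz2 (log2 4.33, SE 0.54, adjusted p = 0.00126) and Fabp6 (log2 −4.88, SE 0.89, adjusted p = 0.0478), the latter lost without CR ileum 1, 3 or 4, GF ileum 1, CV ileum 1, 2 or 3, CR colon 2, GF colon 1, 2 or 3 or CV colon 1 or 3 (adjusted p 0.0503 to 0.238). The call of Cxcl12 was lost without GF ileum 1 (adjusted p = 0.0575). Among lists, the interaction of CR minus GF was called for small intestine regional markers (median −2.65, adjusted p = 1.66e-07, or 0.191 with an estimated correlation) and for T cell markers (−1.02, adjusted p = 3.85e-05, or 0.707 with an estimated correlation). These are among 10 list calls, of which there were 6 without GF ileum 2 or GF colon 2.

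The interaction of CR minus GF called 33 genes and loci, 21 higher and 12 lower, and FPKM as deposited gave 74 and 18. The count was 679 without GF ileum 2, 525 without GF colon 2 and 93 without CR colon 1. It was 21 without CR ileum 1 or CV colon 2, 16 without CR ileum 2, and 19 without CR ileum 4, GF ileum 1, CV ileum 3 or CR colon 2. It was 17 without CV ileum 1, 18 without CR colon 3 and 20 without GF colon 3. The interaction of CV minus GF called 17, with 322 without GF ileum 2, 33 without CR colon 1 and 28 without GF colon 1. That count was 8 without CR ileum 1, GF ileum 1, CV ileum 2 or CV colon 3. It was 9 without CR ileum 3, CR ileum 4, CV ileum 1, CV ileum 3, CR colon 2 or CV colon 2, and 10 without GF colon 2 or GF colon 3.

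Colon and ileum were compared over all groups as a reference for the size of an effect. Fabp6 was at 111 ± 146 in colon and 17520.0 ± 6011 in ileum (log2 −8.98, SE 0.35, adjusted p = 6.90e-12), as mean ± SD with n = 9 each. Lyz1, a Paneth cell lysozyme gene, was at 5.08 ± 6.89 and 1361 ± 802 (log2 −8.38, adjusted p = 1.40e-10). Reg3g was at 22.8 ± 16.99 and 1858 ± 779 (log2 −6.54, adjusted p = 4.69e-09) and Apoa1 at 50.3 ± 73.2 and 7385 ± 2154 (log2 −8.87, adjusted p = 1.54e-09). Sis was at 8.72 ± 9.08 and 658 ± 299.7 (log2 −6.63, adjusted p = 3.82e-10) and Gata5, a transcription factor of the small intestine, at 0.655 ± 0.5003 and 45.2 ± 8.28 (log2 −4.82, adjusted p = 2.74e-13). Higher in colon were the carbonic anhydrase genes Car1 (3236 ± 1342 and 7.87 ± 20.8, log2 10.10, adjusted p = 2.89e-09) and Car2 (log2 8.12, SE 0.22, adjusted p = 1.65e-13). The homeobox gene Hoxb13 (163 ± 57.5 and 0.0235 ± 0.03197, log2 7.24, adjusted p = 1.27e-14) and the water channel gene Aqp8 (163 ± 80.6 and 0.0838 ± 0.103, log2 7.06, adjusted p = 1.18e-12) were higher as well. Saa1 was at 1306 ± 807 and 26.5 ± 40.7 (log2 6.95, adjusted p = 1.06e-07). Retnlb was at 123 ± 151 and 0.861 ± 2.43 (log2 5.74, adjusted p = 2.57e-09), and Insl5, a hormone gene of colonic endocrine cells, at 41.6 ± 19.2 and 0.0534 ± 0.0801 (log2 5.21, adjusted p = 1.65e-11).

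All 12 colon regional markers were higher in colon (median 4.77, adjusted p = 5.32e-09, or 0.00962 with an estimated correlation), and 15 of 17 small intestine regional markers were lower (median −4.82, adjusted p = 5.32e-09, or 0.103 with an estimated correlation). Absorptive enterocyte genes had 13 of 13 lower in colon (median −3.22, adjusted p = 3.80e-08, or 0.132 with an estimated correlation), and lipid absorption 15 of 17 (median −3.89, adjusted p = 8.74e-06, or 0.144 with an estimated correlation). Transport genes induced by short-chain fatty acids had 10 of 12 higher (median 2.06, adjusted p = 2.01e-04, or 0.132 with an estimated correlation). In all, 3406 genes and loci were higher and 3245 lower in colon, 5438 and 1940 with FPKM as deposited, and the groups' libraries did not overlap for 2372 (chance gives 0.00411% of genes).

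Accessible chromatin was compared between the same groups by the share of DNase-seq peaks that a pair of libraries has in common. Within ileum, pairs of the same group shared 88.54% of peaks and pairs of different groups 86.53%, a difference of 2.01 points (one-sided exact permutation p = 0.00905, 2100 arrangements). Within colon the shares were 86.5% and 85.64%, a difference of 0.865 points (one-sided exact permutation p = 0.121, 280 arrangements), or 2.76 points (exact p = 0.00714) where peaks had to overlap by at least 50%. CR and GF ileum libraries shared 88.7% ± 1.9 (SD, 12 pairs), against 87.3% ± 2.92 among CR (6 pairs) and 91.33% ± 0.47 among GF libraries (3 pairs). CV ileum libraries, whose lists have narrower peaks, shared 88.22% ± 0.92 (SD, 3 pairs) among themselves, 85.23% ± 2.51 with CR (12 pairs) and 85.36% ± 1.43 with GF (9 pairs). CR and GF colon libraries shared 86.54% ± 2.62 (SD, 9 pairs). Between ileum and colon the share was 72.24%, against 86.53% within a tissue, a difference of 14.29 points (one-sided exact permutation p = 1.08e-05, the smallest that 92378 arrangements can give). Without GF ileum 2 the ileum difference was 1.46 points (exact p = 0.0524). The colon difference was −0.024 without CR colon 1, −0.032 without CR colon 2, 1.69 (exact p = 0.0286) without CV colon 1 and 2.11 (exact p = 0.0214) without CV colon 3. Whether the ileum and colon differences differ was not tested.

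The duodenum of CR mice shared 78.83% ± 2.14 (SD, 8 pairs) of its peaks with CR ileum and 71.1% ± 1.42 (6 pairs) with CR colon, a difference of 7.73 points (two-sided exact permutation p = 0.0286, the smallest that 35 arrangements can give), or 7.08 points (exact p = 0.0571) with an overlap of at least 50%. Without any 1 of the ileum or colon libraries the difference ran from 7.06 to 8.44, with too few arrangements for an exact p under 0.05.

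**Figure D4:**
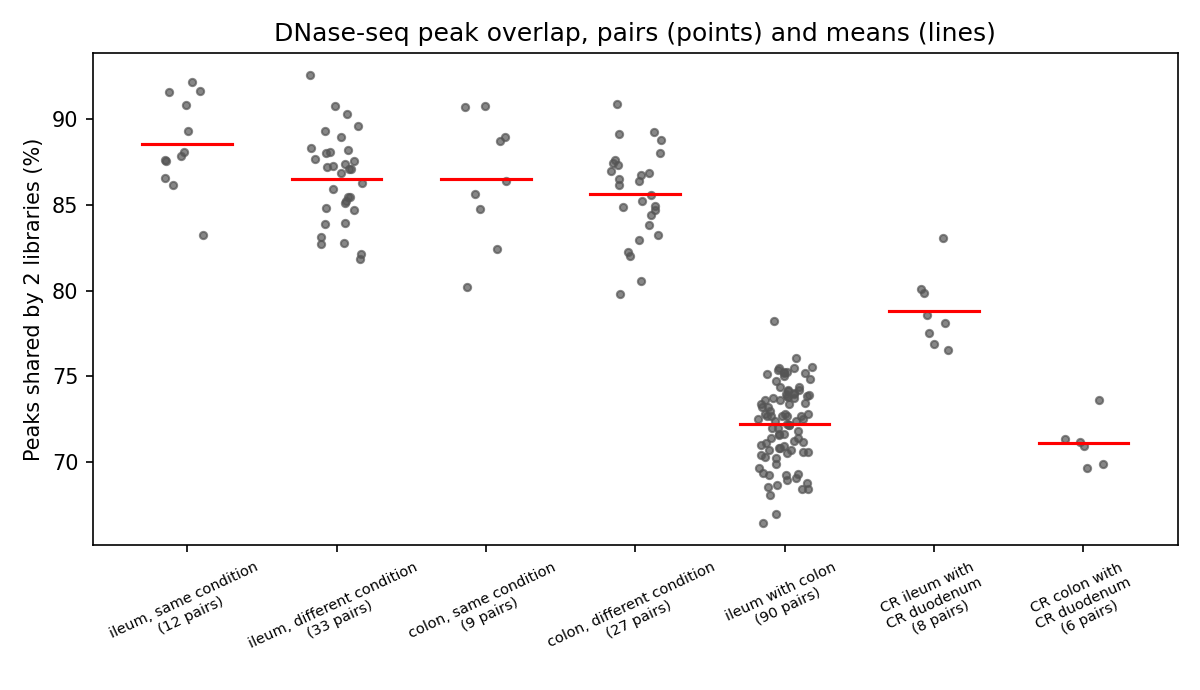
Percent of DNase-seq peaks shared by each pair of libraries, with points for pairs and red lines for class means. Pairs of the same ileum group lie at 83.24 to 92.15% and pairs of different ileum groups at 81.85 to 92.54%, while pairs of ileum with colon lie at 66.44 to 78.23%.

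Merged peaks gave 132470 regions in ileum, 64807 of them (48.9%) in all 10 lists, and 138248 in colon, 64277 of them (46.5%) in all 9. Of the ileum regions, 180 were present in all CR and no GF lists and 480 in all GF and no CR lists. One CR region lies on chromosome 16 (58574075 to 58575053, 95267 bp from Cpox) and one GF region on chromosome 3 (157112737 to 157113288, 116567 bp from Ptger3). In colon the counts were 1063 for CR and 950 for GF, with a CR region 36303 bp from Dapk3 on chromosome 10 (80608155 to 80609448) and a GF region 210237 bp from Btbd3 on chromosome 2 (138323396 to 138324045). CV and GF were parted by 1775 CV and 4039 GF regions in ileum and by 250 and 825 in colon, and CR and CV by 1276 CR and 956 CV regions in ileum and 1214 and 305 in colon. The CV lists had narrower peaks, with a median width of 539 to 670 bp against 771 to 1025 bp in the CR and GF lists. Ileum and colon were parted by 4420 regions in all ileum and no colon lists and 4547 of the opposite kind. One of ileum lies 41302 bp from Fam110a on chromosome 2 (151748905 to 151753831), and one of colon 23695 bp from Il1r1 on chromosome 1 (40396718 to 40398053). Their mean peak ranks were 5816 and 4713, against 51008 to 66330 for the CR and GF regions named above. A list left out relaxes the rule. For CR and GF ileum the count was 1446 without CR ileum 1, 1212 without CR ileum 2, 1295 without CR ileum 4, and 1380, 1169 and 1433 without GF ileum 1, 2 and 3. For CR and GF colon it was 3496 without CR colon 1, 6217 without CR colon 3, 5461 without GF colon 1 and 3288 without GF colon 3. CV and GF colon had 3172 without GF colon 1, 1950 without GF colon 3, and 2245, 2875 and 3031 without CV colon 1, 2 and 3. CR and CV had 3575 in ileum without CR ileum 1, and 3545, 3846 and 3564 without CV ileum 1, 2 and 3. In colon they had 2534 without CR colon 1, 4084 without CR colon 3, and 4228, 2471 and 3685 without CV colon 1, 2 and 3.

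Fabp6, whose transcript differed between CR and GF colon, had 3 ± 0 peaks within 10 kb in both (SD, n = 3 each), 1.67 ± 0.58 in CV colon (n = 3) and 6.75 ± 0.5 in CR ileum (n = 4). Angptl4 had 4.33 ± 0.58 in CR colon, 3.33 ± 0.58 in GF colon, 7 ± 1.41 in CR ileum and 7.67 ± 1.53 in GF ileum. Retnlb had 2 ± 0 in both CR and GF colon, Apoa1 2 ± 0 and 2.33 ± 0.58, and Lyz2 1 ± 0 in the ileum of CR, GF and CV mice. Car1 had 5.67 ± 2.08 in both CR and GF colon and none in any ileum list. The 138 genes and loci higher in CR colon had 5.42 ± 0.25 peaks in CR and 4.78 ± 0.05 in GF (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The 10532 not called had 5.53 ± 0.12 and 5.24 ± 0.05 (p = 0.1 by the same permutation test). The 115 higher in GF colon had 5.84 ± 0.20 and 5.85 ± 0.34 (exact permutation p = 0.9). In ileum, genes higher in CR (5) had 9.7 ± 0.77 and 8.87 ± 0.23 peaks in CR and GF (exact permutation p = 0.114), and those higher in GF (7) had 6.46 ± 0.89 and 6.67 ± 0.36 (exact permutation p = 0.771, or 0.0286 with the 50% of peaks of highest signal). Genes higher in ileum (3245) had 6.01 ± 0.28 peaks in colon and 7.31 ± 0.16 in ileum (exact permutation p = 1.08e-05, the smallest possible). The 4134 not called also had fewer in colon, 4.72 ± 0.18 and 5.05 ± 0.05 (exact permutation p = 3.25e-05). Genes higher in colon (3406) had 5.58 ± 0.25 and 5.44 ± 0.13 (exact permutation p = 0.127, or 0.0484 without CV colon 2). Their difference of 0.145 was 0.245 within 2 kb (exact p = 6.5e-05), −0.434 within 50 kb (exact p = 0.102) and 0.180 with 150 bp windows around summits (exact p = 0.0474).

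Regions present in one tissue alone lay more often near genes higher in that tissue. Of 1939 genes and loci with an ileum region within 10 kb, 50.9% were higher in ileum, against 25.5% of the others (odds ratio 3.03, Fisher's exact test, p = 8.35e-100 adjusted over 12 tests). Of 1192 with a colon region, 41.7% were higher in colon, against 30.3% (odds ratio 1.64, adjusted p = 2.62e-14). Of 635 with a CR colon region, 16 (2.5%) were higher in CR colon, against 1.2% (odds ratio 2.13, adjusted p = 0.0222). Genes are not replicates, and other library splits gave more regions (2205) and calls (287), so no link is shown. Of 213 with a GF colon region, 1.4% were higher in GF, against 1.1% (adjusted p = 0.909). In ileum, 0 of 101 with a CR and 0 of 194 with a GF region were among the 12 calls.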

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

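The tests of explanations for the 3 patterns weighed here were chosen after the results were seen. The counts over other splits of the libraries, the screen for single libraries and the tests of a difference between tissues were fixed before the data were examined.

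The 6 CV libraries differed from the GF libraries in the same transcripts in both tissues, with 113 genes and loci called in both and all 113 in the same direction, among them Apex1, Fbxo6, Pkig and Csl. Matching of entries between the tables is argued against as the cause for most named calls, since 20.8% of those in ileum and 16.8% in colon were matched differently in the CV tables, against 13.7% of the named genes tested, but a part of them and the calls of unnamed loci (87 of 200 in colon) stay open. Reads placed differently between related gene copies may account for part of the pattern: names of copies (predicted genes, pseudogenes and related sequences) made up 31% of those named calls and 2.5% of the named genes tested (odds ratio 22.7, Fisher's exact test, p = 2.76e-29 adjusted over 7 comparisons), against 2.4% for CR minus GF colon. Submitters' steps that differed for the CV libraries cannot be told apart from colonization, since all CV libraries form 1 group; 11 loci, such as Snx22 and Zfp385c, were at 0 in all libraries of one side and at 2 or more in all of the other, against at most 1 in 7056 splits. An effect of late colonization itself stays open and untested.

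Transcripts typical of the small intestine were higher in GF than in CR colon, such as Fabp6, Apoa1, Sis and Slc10a2. Ileal cells carried into the GF colon are argued against as the whole cause for the bile acid transporters: the lowest ileal share that Slc10a2, Osta and Ostb need is 9.15, 4.18 and 4.71% in the 3 GF colon libraries, while the whole level of 11 of 22 other transcripts at 100 or more in GF ileum allows less in each, at most 1.77% for Fabp6 and Apoa1, 2.08% for Anpep and 0.475% for the Paneth cell gene Lyz1. For 13 such transcripts picked for a low level in CR colon, Fabp6, Apoa1 and Anpep among them, these cells could supply the level seen, and their median share of 1.38% (0.22 to 4.6%) cannot decide. The sex of the mice cannot be told apart from the group with 1 library: against GF colon 1, the GF colon library that expresses Y-linked genes, the 10 called genes had a median log2 of −3.11, all negative and 5 called, near the −3.22 against all GF colon libraries. A response of the colon to the absence of microbes stays open and untested.

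T cell transcripts were higher in CR than in GF ileum as a list of 21 genes, with a median log2 of 1.28 (quartiles 0.96 to 1.51; adjusted p = 5.41e-14, or 0.741 with an estimated correlation), while Cd7 and Ptprc did not pass the test singly. A single CR or GF library as the cause is argued against, since the median was 0.836 or more with any 1 of the 6 left out and all 21 genes stayed positive. A lower share of epithelial cells in the CR ileum cannot be excluded: the stroma list had a median of 0.036 and at most 0.246 with 1 library left out, but only 1 of its 7 genes reached 5 scaled FPKM. The difference between the lists, 1.32, had an exact permutation p of 0.133 (15 splits, smallest possible 0.0667). No cell sort is stated in the labels, and more intraepithelial lymphocytes in CR mice stays open and untested.

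For CR minus CV ileum 1 of 35 splits, the real one, called 311 genes and loci, and the highest other called 13. For colon minus ileum 1 of 100 splits, the real one, called 6651, and the highest other 4489. Both shares are under 0.05, uncorrected over the split tests. Splits of 3 against 3 are too few for a share under 0.05: the real and highest other values were 253 and 287 for CR minus GF colon (2 of 10 splits as large), 200 and 2 for CV minus GF colon (1 of 10), and 703 and 6 for CR minus CV colon (1 of 10). For CR minus GF colon another split also called more, so chance stays open. The split with 287 set CR colon 1, GF colon 1 and GF colon 3 against CR colon 2, CR colon 3 and GF colon 2, which points to a structure of the samples other than their group.

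Regions that part ileum and colon numbered 8967, against at most 1019 in the other splits (1 of 92378 as large), so chance is excluded. For CR against CV ileum (2232, highest other 1341) 1 of 35 splits, uncorrected, does not exclude it. For CR against GF ileum (660, highest other 785) 3 of 35 parted as many, so chance is not excluded. Of the others, one set CR ileum 4 with GF ileum 1 and 2 against the rest, and one set CR ileum 1 with the 3 GF lists. Splits of 3 against 3 are again too few for a share under 0.05, and CV against GF ileum had 5814 and 628 (1 of 10 as large). In each colon comparison another split also parted more regions, so chance stays open. The values were 2013 and 2205 for CR against GF (2 of 10), 1075 and 2058 for CV against GF (3 of 10), and 1519 and 2363 for CR against CV (2 of 10). The splits with 2205, 2058 and 2363 each set the first library of one group with the first and second of the other. This points to structure other than the groups.

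Among 33 genes, 5 lists and 6 library measures screened in CR ileum, 3 genes and 1 list had 1 library far from the other 3, where chance gives about 1 in 20. The gap to the nearest library was 0.964 of the range for Bambi-ps1 (18.7 against 6.06 to 6.52 scaled FPKM), 0.99 for Fut2 (37.3 against 1.15 to 1.52), 0.991 for Retnlb (7.33 against 0.041 to 0.106) and 0.948 for the mean of the tuft cell list (4.25 against 2.47 to 2.56).

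The effect of CR against GF differed between colon and ileum by test for 33 genes and loci, among them Trmt112 (log2 4.81), S100a14 (2.17), Arrdc4 (−1.24), Cxcl12 (−1.71), Vnn1 (−2.47) and Tgfbi (−3.52). For CV against GF it differed for 17, among them Lyz2 (log2 4.33), Tmed3 (0.95), Mrps31 (−0.99) and Fabp6 (−4.88). Cxcl12 lost its call without GF ileum 1 (adjusted p = 0.0575), and Tmed3 without CR ileum 1, 3 or 4, GF ileum 1, CV ileum 1 or 3, CR colon 2, GF colon 2 or 3 or CV colon 2 or 3 (adjusted p 0.0533 to 0.158). Mrps31 lost it without CR ileum 1, 2, 3 or 4, GF ileum 1, CV ileum 1, 2 or 3, CR colon 2 or 3, GF colon 1 or 2 or CV colon 1, 2 or 3 (adjusted p 0.0689 to 0.274), and Fabp6 without CR ileum 1, 3 or 4, GF ileum 1, CV ileum 1, 2 or 3, CR colon 2, GF colon 1, 2 or 3 or CV colon 1 or 3 (adjusted p 0.0503 to 0.238). Without GF ileum 2 the counts of 33 and 17 were 679 and 322. CV colon 1 listed 4560 assembled entries under 300 bp (11.9%, not used), against 506 to 847 in the other tables.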

How the results depend on the processing

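Of 28849 values of single genes, loci, lists and shares of loci with a DNase-seq peak over 46 settings, 27685 (96.0%) kept their direction and their side of the threshold, 590 fell below it, 369 passed it, 205 moved and 0 reversed. Of the called genes and loci named by the rule, the number called in every setting was 0 of 9 for CR minus GF ileum, 18 of 24 for CV minus GF ileum, 15 of 20 for CR minus CV ileum, 11 of 33 for CR minus GF colon, 17 of 26 for CV minus GF colon, 13 of 35 for CR minus CV colon and 83 of 95 for colon minus ileum. For the values that follow, the cause was not tested unless the construction of the setting shows it, as where fewer loci or libraries enter. Comparing an equal number of peaks from every list was not run, since all lists hold 100000. FPKM without counts limits what the low transcripts can show.

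Counts of called genes that moved by over 1.5 times are given with the setting. With a pseudocount of 0.1, the interaction of CV minus GF called 9 and the overlap of CR minus GF and CV minus GF calls was 1 in ileum. With no filter on low values, CR minus GF ileum called 3, that interaction 37 and the ileum overlap was 1. A filter of 5 scaled FPKM, which tests fewer loci, gave 140 for CR minus GF colon and a colon overlap of 14. FPKM as deposited gave 484 for CR minus GF colon, 1437 for CR minus CV colon, and 92 and 9 for the interactions of CR minus GF and CV minus GF. Quantile normalization gave 384, 1058 and, for the interaction of CR minus GF, 56, with an ileum overlap of 1. A separate fit per tissue, with fewer residual degrees of freedom, gave 4 for CR minus GF ileum, 41 for CR minus GF colon, 255 for CR minus CV colon, and overlaps of 1 in ileum and 6 in colon.

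Library weights (limma's arrayWeights) gave 0 for CR minus GF ileum (622 at an unadjusted p under 0.05), 2467 for CR minus CV ileum, 2922 for CR minus GF colon, 592 for CV minus GF colon, 2960 for CR minus CV colon, 414 for the interaction of CR minus GF and a colon overlap of 203. The labels do not say that replicate numbers pair the libraries. Once group means were removed, a correlation above 0.1 was found for 1 of 7 (ileum), 1 of 9 (colon) and 2 of 8 (between tissues) same-number pairs in RNA-seq and for 1 of 9, 2 of 9 and 3 of 13 in DNase-seq. The 3 between tissues in DNase-seq are those of CR libraries numbered 1 (0.187, 0.18 and 0.105), and such pairs averaged 0.067 against −0.028 for other numbers. Replicate numbers as a block gave 4 for CR minus GF ileum, 121 for CV minus GF ileum, 184 for CR minus CV ileum, 90 for CR minus GF colon and 366 for CR minus CV colon. With the block the interactions called 7 and 4, the overlaps were 1 in ileum and 7 in colon, and the difference of the duodenum was 7.73 with an exact p of 0.125, the smallest that 8 arrangements can give. A threshold of 1 on the absolute log2 difference left a colon overlap of 6. Of 216 list tests over 9 contrasts, camera called 63, camera with an estimated correlation 1 and fry 25.

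Alternatives chosen after seeing the data moved the following. With GF colon as its Y-expressing library alone, the interactions called 397 and 26, and the overlaps were 1 in ileum and 53 in colon. Named genes alone, a smaller set, gave 92 for CV minus GF ileum, 158 for CR minus CV ileum, 118 for CV minus GF colon, 431 for CR minus CV colon, 3838 for colon minus ileum, 17 and 2 for the interactions and an ileum overlap of 1. Without loci listed at 0 and at 5 or more, the interactions called 11 and 2. Without overlapping loci, CV minus GF ileum called 116, CR minus CV ileum 207, CV minus GF colon 130, the interactions 8 and 5, and the ileum overlap was 1. A fit without CV gave 7 for CR minus GF ileum and 123 for CR minus GF colon. Windows of 150 bp around peak summits gave 1140 separating regions for CR and GF ileum and 1798 for CV and GF colon.

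With 1 RNA-seq library left out, the lowest and highest counts were 7 and 100 for CR minus GF ileum, 127 and 1100 for CV minus GF ileum, 193 and 376 for CR minus CV ileum, 63 and 455 for CR minus GF colon, 146 and 248 for CV minus GF colon, 266 and 1304 for CR minus CV colon, and 6120 and 6721 for colon minus ileum. They were 16 and 679 for the interaction of CR minus GF, 8 and 322 for that of CV minus GF, 0 and 80 for the ileum overlap, 6 and 27 for the colon overlap, and 41 and 71 for list calls. Without GF ileum 2 the values were the highest for CR minus GF ileum, CV minus GF ileum, both interactions and the ileum overlap, and the lowest for list calls. Leaving out GF ileum 1 or 2 leaves a lone library, which the fit assumes to vary like the other groups. The lowest and highest in colon came without CR colon 2 and GF colon 2 for CR minus GF, without CR colon 3 and CR colon 1 for CR minus CV, and the lowest colon overlap without CV colon 3. Without CV ileum 1, CR minus CV ileum was at its lowest.

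For DNase-seq, the 50% of peaks with the highest signal gave 393 separating regions for CR and GF ileum, 975 for CR and GF colon, 587 for CV and GF colon, 739 for CR and CV colon and 4252 for ileum and colon. In that setting the differences in peaks at genes of CR minus GF were 0.0 (ileum, higher in CR), −0.738 (ileum, higher in GF, exact p = 0.0286) and 0.038 (colon, higher in GF). An overlap of at least 50% gave a colon difference by condition of 2.76 (exact p = 0.00714), a duodenum difference of 7.08 (exact p = 0.0571) and separating regions of 1409 for CR and GF ileum, 17369 for CV and GF ileum, 5608 for CR and CV ileum, 3944 for CV and GF colon, 5475 for CR and CV colon and 5884 for ileum and colon. Peaks within 2 kb of genes higher in colon differed by 0.245 (exact p = 6.5e-05), and within 50 kb by −0.434, with 0.290 for genes higher in GF colon.

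With 1 DNase-seq list left out, the lowest and highest differences were 1.46 and 2.74 by condition in ileum, −0.032 and 2.11 by condition in colon, 13.99 and 14.83 by tissue and 7.06 and 8.44 for the duodenum. Separating regions were 660 and 1446 for CR and GF ileum, 5814 and 8481 for CV and GF ileum, 2232 and 3846 for CR and CV ileum, 2013 and 6217 for CR and GF colon, 1075 and 3172 for CV and GF colon, 1518 and 4228 for CR and CV colon, and 8967 and 10242 for ileum and colon, since fewer lists make the rule easier to meet. Differences in peaks at genes were 0.467 and 1.07 (CR minus GF ileum, higher in CR), −0.524 and 0.191 (higher in GF), 0.539 and 0.778 (CR minus GF colon, higher in CR), −0.171 and 0.168 (higher in GF), 0.102 and 0.187 (higher in colon), and −1.36 and −1.24 (higher in ileum). The ileum difference by condition was lowest without GF ileum 2, and the colon one without CR colon 2 and highest without CV colon 3.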

Other observations

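Colon differed from ileum in secretory and metabolic genes as well (n = 9 RNA-seq libraries each, mean scaled FPKM ± SD). Of 7 goblet cell genes 6 were higher and 1 lower in colon (median log2 1.06, adjusted p = 0.0103, or 0.281 with an estimated correlation), such as Creb3l1, a transcription factor of secretory cells, at 106 ± 29.5 and 20.8 ± 4.72 and the kallikrein gene Klk1 at 1143 ± 258 and 95.2 ± 26.4. Mucin-type glycosylation had 8 of 13 higher and 1 lower (median 0.58, adjusted p = 0.0103, or 0.267 with an estimated correlation), with the galactosyltransferase gene B3galt5 at 56.1 ± 10.8 and 0.204 ± 0.119 and the sulfotransferase gene Gal3st2 at 18.4 ± 6.44 and 151 ± 39.8. Cholesterol biosynthesis had 10 of 12 lower in colon (median −0.89, adjusted p = 0.00165, or 0.53 with an estimated correlation). Bile acid transport had 5 of 6 lower (median −3.83, adjusted p = 9.31e-04, or 0.103 with an estimated correlation).

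Some cell markers differed too. Camera called none of the enteroendocrine (4 higher, 7 lower of 17), stem cell, T cell and MHC class II lists. All 3 tested Paneth cell genes were lower in colon, with the matrix metalloproteinase gene Mmp7 at 0.876 ± 0.358 and 77.4 ± 32.5 (log2 −5.34, adjusted p = 3.74e-11). Neurotensin (Nts, 3.36 ± 2.22 and 80.4 ± 49.5, log2 −4.06, adjusted p = 4.16e-08) and secretin (Sct, 22.96 ± 8.69 and 103 ± 33.8, log2 −2.15, adjusted p = 1.34e-07) were lower in colon. Of stem cell genes, Olfm4 was at 1.902 ± 4.19 and 149.7 ± 50.5 (log2 −6.28, adjusted p = 3.09e-09), Lgr5 at 2.07 ± 0.461 and 3.66 ± 0.535 (log2 −0.62, adjusted p = 1.30e-04) and the guidance receptor gene Ephb3 at 9.21 ± 2.55 and 3.02 ± 0.802 (log2 1.31, adjusted p = 1.21e-07). Of T cell genes 2 were higher and 2 lower. The granzyme gene Gzma was at 2.35 ± 1.94 and 29.1 ± 35.9 (log2 −2.38, adjusted p = 7.76e-04). The MHC class II gene H2-Ab1 was at 8.32 ± 9.41 and 125 ± 178 (log2 −2.90, adjusted p = 0.00107). Mki67 did not pass the test (11.5 ± 3.12 and 16.2 ± 5.46, log2 −0.36, adjusted p = 0.0988). Of B cell markers 2 of 2 were higher, of acinar pancreas markers 1 of 4 higher and 2 lower, and erythrocyte gene Bpgm was lower.

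The highest peak signal of a CV list was 2.0 to 2.62, against 0.86 to 1.45 in the CR and GF lists. The GF colon DNase-seq lists held 5 to 7 peaks within 4 Y-linked genes, whereas the RNA-seq tables of GF colon 2 and 3 listed Kdm5d, Eif2s3y and Uty at 0.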
